A study of Mus musculus with 18 samples.

How the data were processed

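RNA from mouse MCA205 cells, TC1 cells and day 8 TC1 tumours was sequenced in 18 libraries, 3 for each of 6 groups, with column-purified RNA and Illumina libraries per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore, Bowtie2, featureCounts and the mm10 build, without versions or roles, and the program that made the deposited values is not given in the sources used here. Each of 3 deposited tables, 1 for each comparison, lists transcripts with FPKM values and estimated count values, per the file headers, and 0 columns were without a sample. The FPKM values were scaled by the authors to transcript length and library size. The estimated counts deposited by the authors were already whole numbers, so rounding changed none of them, and they equalled FPKM multiplied by transcript length and 1 factor per library. Direct tallies would meet that relation too, so it does not tell tallies from estimates. Columns labelled KO were taken as the libraries that the sample titles label sgNAT10.

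The tables held 87073, 89209 and 87912 transcripts of 30365, 30386 and 30631 genes for MCA205 cells, TC1 cells and tumours. Transcript values were summed per gene, so reads of near-identical relatives and of overlapping or antisense genes rest on the authors' assignment, with no strand setting given in the sources used here. Of the genes, 99.7% had an identifier in the reference annotation used, and coordinates are those of mm10. Libraries held between 51661298 and 78501790 estimated counts. Libraries of a group were compared with each other. They had exactly equal counts for at most 1.83% of the genes kept for testing, and differed by more than sampling noise, with a lowest chi-square ratio of 5.22.

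In each comparison the 6 libraries of 1 table were fitted with edgeR quasi-likelihood tests, with TMM factors and the default expression filter, which left 18101, 18823 and 19244 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of genes are from this test. Levels are means ± SD of summed FPKM over 3 libraries. Differences of effects were tested as interaction contrasts over 12 libraries, each effect being taken within its own table, since the tables may have been normalised separately. Pathway and cell type lists, 19 and 14 in number, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Some lists share members, so their results are not independent. Overlaps of calls between comparisons were tested with a one-sided hypergeometric test across genes. No label says that the libraries of a group come from separate cultures or animals. P-values therefore measure the spread between libraries, which may be technical. No sample title names separate sgNAT10 clones, so differences between cell populations that arose apart from the guide cannot be told from its effect.

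Tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took Nat10, Myc, Cdk2 and Dnmt1, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM, without unnamed models or pseudogenes, up to 4 members of each list with the smallest p, and up to 5 genes for each kind of overlap or direction of difference. Of the list members taken by the rule, a selection is printed. Lists of liver, intestine, kidney, heart, airway and brain genes, the pair of MCA205 cells and tumours, a covariate for liver and intestine level and a fit without MCA205 wild type 1 and sgNAT10 2 were added after the data were seen.

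Alternatives were RLE size factors, library size alone, no filter, a filter of 1 CPM in the 3 libraries of a group, DESeq2, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of at least 1 FPKM in 3 libraries, a replicate block, dispersion over all 18 libraries, a 2-fold minimum, fry, and each library left out. The edgeR step was tested on simulated counts with 200 changed genes, 100 for each fold size. The changed genes were drawn from those above a minimum mean count, so the rates do not cover genes with few counts. Far fewer genes changed than were called in the data, so the rates may differ there. It recovered 58% of 2-fold and 76% of 4-fold changes for MCA205 cells among 17407 genes, 56% and 91% for TC1 cells among 18327 genes, 46% and 87% for tumours among 18671 genes, and 49% and 81% for the difference between MCA205 and TC1 cells among 19805 genes. On the same simulated counts DESeq2 recovered 77%, 68% and 72% of 2-fold changes for MCA205 cells, TC1 cells and tumours. With edgeR unchanged genes made up 2.9%, 6.37%, 6.99% and 1.52% of the calls. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The values of 1 gene chosen by the rule for named genes are not reported here.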

Results

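RNA was sequenced from 18 mouse libraries in 6 groups of 3. Wild-type cells and cells in which Nat10 had been targeted by CRISPR (labelled sgNAT10) were compared in MCA205 cells in culture, in TC1 cells in culture, and in subcutaneous tumours grown from TC1 cells and taken on day 8. MCA205 is a methylcholanthrene-induced mouse fibrosarcoma line. TC1 is commonly described as a lung epithelial line transformed with papillomavirus oncogenes, although the labels call these cells fibrosarcoma too. NAT10 is the enzyme that places N4-acetylcytidine on RNA. The series title names the pathway in question, from NAT10 through MYC, CDK2 and DNMT1 to type I interferon responses, so the comparisons ask how transcripts of that pathway and of the interferon response differ between the genotypes. Totals ranged from 51661298 to 78501790 estimated counts per library. The 10 most abundant genes took between 4.56% and 6.1% of a library.

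Nat10, on chromosome 2 from 103721256 to 103761270 in mm10, was not called as changed by edgeR in any of the 3 comparisons. In MCA205 cells it was listed at 14.2, 12.5 and 13.8 FPKM in the wild-type libraries and at 13.2, 13.6 and 13.6 FPKM in the sgNAT10 libraries. The TC1 cells held 13.9, 14.1 and 15.9 FPKM against 14.2, 12.4 and 11.7 FPKM, and the tumours 14.8, 16.2 and 15.3 FPKM against 12.3, 16.1 and 16.3 FPKM. The log2 differences of 0.00, -0.22 and -0.22 had adjusted p of 0.984, 0.161 and 0.336. A guide that shifts the reading frame need not lower the transcript, so these levels do not check the labels, and directions below are those between libraries labelled sgNAT10 and libraries labelled wild type. The full-length coding transcript took 62.6 ± 10.6% of the Nat10 estimated counts in wild-type MCA205 cells and 46.1 ± 6.25% in the sgNAT10 cells (SD, n = 3). In TC1 cells these shares were 58.0 ± 17.2% and 46.2 ± 9.53%, and in the tumours 60.0 ± 11.6% and 57.6 ± 7.52%.

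The genes named beside NAT10 in the title were lower in both sgNAT10 cell lines. In MCA205 cells Dnmt1, the maintenance DNA methyltransferase, fell from 114 ± 9.40 to 48.6 ± 2.52 FPKM, the cell cycle kinase gene Cdk2 from 64.6 ± 9.16 to 18.1 ± 1.07 FPKM, with adjusted p of 1.09e-05 and 4.02e-05. The transcription factor gene Myc fell from 90.6 ± 8.69 to 59.0 ± 5.58 FPKM (adjusted p = 0.00212). In TC1 cells Cdk2 fell from 71.7 ± 12.6 to 34.8 ± 2.68 FPKM, Myc from 229 ± 17.7 to 181 ± 21.9 FPKM and Dnmt1 from 90.9 ± 2.81 to 73.2 ± 0.535 FPKM, with adjusted p of 0.000907, 0.0103 and 0.00231. The TC1 call for Myc was lost without wild type 1, wild type 3, sgNAT10 2 or sgNAT10 3, where its log2 change was -0.26, -0.34, -0.35 and -0.37, and that for Dnmt1 without sgNAT10 2 or sgNAT10 3, at -0.24 each. In the tumours Cdk2 went from 21.1 ± 1.09 to 17.1 ± 1.95 FPKM (adjusted p = 0.0451) and Dnmt1 from 24.3 ± 6.04 to 17.2 ± 2.28 FPKM (adjusted p = 0.0489). Myc stood at 57.1 ± 7.34 and 56.9 ± 8.02 FPKM (adjusted p = 0.539). These tumour calls for Cdk2 and Dnmt1 lay at the threshold. That for Cdk2 was lost without wild type 1, wild type 2 or any sgNAT10 library, at log2 changes between -0.48 and -0.34, and that for Dnmt1 without wild type 2, wild type 3 or any sgNAT10 library, at log2 changes between -0.68 and -0.44. Both were also lost with RLE size factors or library sizes alone. As a list the 4 title genes had 3 members lower in MCA205 cells (adjusted p = 2.37e-05, and adjusted p = 0.0714 with an estimated correlation), 3 lower in TC1 cells (adjusted p = 0.122) and 2 lower in the tumours (adjusted p = 0.123), the same numbers when adjusted over the list alone. These p are camera's. Fry, which tests whether the genes of a list move on balance in 1 direction and not against other genes, called the list downward in MCA205 cells (adjusted p = 0.000243) and TC1 cells (adjusted p = 0.00024), with an adjusted p of 0.0528 in the tumours. Without wild type 1 the list passed camera in TC1 cells at an adjusted p of 0.0338. The list comes from the title of this series and is not independent evidence of its direction.

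**Figure D1:**
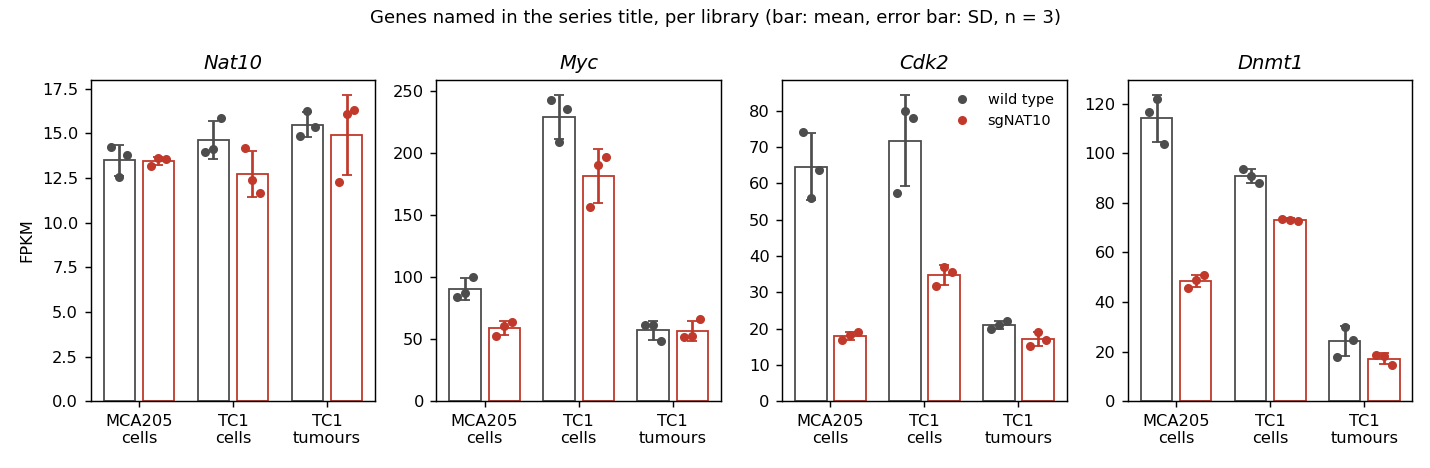
FPKM of Nat10, Myc, Cdk2 and Dnmt1 on linear axes that start at 0, with bars at the group mean, error bars of 1 SD (n = 3) and 1 point for each library, for wild-type and sgNAT10 libraries of MCA205 cells, TC1 cells and TC1 tumours. Nat10 overlaps between genotypes in each of the 3 comparisons, while Dnmt1 in MCA205 cells falls from 114 to 48.6 FPKM.

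In MCA205 cells the sgNAT10 libraries had more transcript of interferon-induced genes and of inflammatory cytokines and NF-kB targets. The chemokine gene Cxcl10 rose from 65.4 ± 5.96 to 752 ± 9.41 FPKM and Irf7, which amplifies interferon production, from 9.60 ± 0.783 to 81.1 ± 0.560 FPKM (SD, n = 3). The matrix protein gene Mgp fell from 139 ± 5.33 to 2.47 ± 2.62 FPKM and Uhrf2, a reader of hemimethylated DNA, fell by 5.99 on the log2 scale. Of 18101 genes tested, 3841 were higher and 3514 lower, and 1170 and 619 of them changed at least 2-fold. The groups of 3 did not overlap for 52.6% of the tested genes, against 10% for chance.

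The 10 largest rises in MCA205 cells by the fixed rule held several interferon-inducible genes. Ifi206 went from 0.343 ± 0.0151 to 16.3 ± 1.23 FPKM, its relative Ifi209 rose by 5.33 on the log2 scale, and the antiviral GTPase gene Mx1 went from 0.622 ± 0.139 to 20.4 ± 1.01 FPKM. The placental prolactin family members Prl2c2 and Prl2c3 went from 24.2 ± 2.57 to 1316 ± 70.7 FPKM and from 3.98 ± 0.865 to 270 ± 10.2 FPKM. Their sequences are nearly alike, as are those of the Serpina3 and Ifi200 families, so the split of reads among such relatives is uncertain. Serpina3m (log2 change 6.43), Serpinb2 (6.08), the pluripotency-associated Dppa4 (5.24), the T cell checkpoint receptor gene Havcr2 (5.21) and the natriuretic peptide gene Nppb (5.12) made up the rest. The falls were led by the creatine synthesis gene Gatm, from 19.6 ± 1.29 to 0.240 ± 0.244 FPKM, and Arhgef28, from 12.1 ± 1.24 to 0.178 ± 0.130 FPKM. Cpt1c (-6.13), the imprinted genes Phlda2 (-6.07) and Snrpn (-5.30), Fbln1 (-5.54), Tmem121 (-5.50) and the glutathione transferase gene Gstt1 (-4.89) followed. Their adjusted p lay between 2.21e-07 for Ifi206 and 0.0141 for Gstt1, and only the call for Gstt1 was lost in a fit that left 1 library out (sgNAT10 1, log2 change -4.72).

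Among the type I interferon-stimulated genes of the fixed list, 46 of 52 rose in MCA205 cells and 2 fell (46 and 3 adjusted over the list alone), with a median log2 change of 2.01 (adjusted p = 8.31e-146, and adjusted p = 0.0063 with an estimated correlation). Oas2, which makes an activator of RNase L, rose from 1.65 ± 0.0305 to 37.0 ± 1.63 FPKM, Ifit3b from 1.55 ± 0.136 to 42.2 ± 1.20 FPKM and the signalling gene Stat2 from 9.77 ± 0.429 to 43.8 ± 1.08 FPKM. The list of interferon-gamma-induced genes had 17 of 21 higher, also over the list alone, with a median of 2.11 (adjusted p = 3.36e-20, and adjusted p = 0.148 with an estimated correlation). Gbp3 rose from 3.03 ± 0.363 to 39.6 ± 1.36 FPKM. Genes of nucleic acid sensing numbered 19 higher and 2 lower of 26 (19 and 4 adjusted over the list alone; median 0.34, adjusted p = 6.09e-10, and adjusted p = 0.0714 with an estimated correlation), with the Z-RNA sensor gene Zbp1 going from 4.21 ± 0.638 to 52.4 ± 1.86 FPKM. Zbp1, Irf7, Ifih1 and other sensing genes are also on the type I list, so these list results are not independent. For MHC class I antigen presentation 16 of 22 rose and 4 fell, also over the list alone (median 1.09, adjusted p = 6.62e-31, and adjusted p = 0.00901 with an estimated correlation). Its members Tap1, Psmb9 and Nlrc5 are also on the interferon-gamma list. H2-T22 went from 32.7 ± 1.25 to 110 ± 0.836 FPKM and the peptide-loading chaperone gene Tapbp from 54.9 ± 1.41 to 136 ± 1.70 FPKM. Inflammatory cytokines and NF-kB targets had 11 higher and 3 lower of 23 (12 and 3 adjusted over the list alone; median 1.14, adjusted p = 1.04e-26, and adjusted p = 0.0063 with an estimated correlation). Ccl7 rose from 23.7 ± 1.21 to 243 ± 9.84 FPKM, and Csf3, the granulocyte growth factor gene, from 0.991 ± 0.0144 to 16.6 ± 0.803 FPKM.

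Cell cycle, DNA methylation and cholesterol genes were lower as lists in sgNAT10 MCA205 cells. In the G2/M list 26 of 27 genes fell, also over the list alone, with a median of -0.47 (adjusted p = 9.90e-17, and adjusted p = 0.297 with an estimated correlation). Cyclin A gene Ccna2 went from 124 ± 6.15 to 69.9 ± 1.90 FPKM and the kinetochore motor gene Cenpe from 20.8 ± 1.02 to 11.8 ± 0.336 FPKM. G1/S genes numbered 15 lower and 3 higher of 31 (17 and 3 adjusted over the list alone; median -0.15, adjusted p = 0.00785, and adjusted p = 0.955 with an estimated correlation). Ccne1, the cyclin partner of Cdk2, was among the 3 that rose, from 19.4 ± 2.27 to 36.0 ± 1.23 FPKM. The DNA methylation machinery had 9 lower and 1 higher of 17 (12 and 1 adjusted over the list alone; median -0.29, adjusted p = 0.00606, and adjusted p = 0.316 with an estimated correlation), with Uhrf2 at a log2 change of -5.99, Dnmt3b at -1.36, Dnmt1 at -1.25 and the thymine glycosylase gene Tdg at -0.54. Of the genes of cholesterol synthesis, 17 of 19 fell and 2 rose, also over the list alone, with a median of -0.67 (adjusted p = 5.78e-19, and adjusted p = 0.231 with an estimated correlation). Hmgcs1, which encodes an early enzyme of the pathway, went from 87.6 ± 4.16 to 45.1 ± 1.83 FPKM.

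Camera with the preset correlation did not call the other pathway lists in MCA205 cells. Fry called 6 of them. These were the p53 targets (adjusted p = 0.00143), germline genes (adjusted p = 0.0051) and matrix genes (adjusted p = 0.0126) upward, hypoxia (adjusted p = 0.00645) and oxidative phosphorylation (adjusted p = 0.018) downward, and the stress response (adjusted p = 0.0465) upward. MYC target genes had 16 lower and 4 higher of 52 (15 and 4 adjusted over the list alone; adjusted p = 0.0711). Hypoxia and glycolysis had 10 lower and 2 higher of 20, also over the list alone (adjusted p = 0.052). Oxidative phosphorylation had 9 lower and 1 higher of 24 (10 and 1 adjusted over the list alone; adjusted p = 0.0711). Leaving out any library except wild type 1 brought the MYC targets and the hypoxia list past the threshold, with adjusted p down to 0.0118 and 0.00383, as did leaving out wild type 3 or any sgNAT10 library for oxidative phosphorylation, down to 0.0034. Ribosome biogenesis had 7 higher and 8 lower of 34 (adjusted p = 0.776) and the unfolded protein and amino acid stress response 8 higher and 6 lower of 19 (adjusted p = 0.782), also over each list alone. Germline genes silenced by DNA methylation had 3 of 6 higher, also over the list alone (adjusted p = 0.287), among them Rhox5, a homeobox gene on the X chromosome, which rose from 9.89 ± 0.684 to 48.5 ± 1.51 FPKM. The p53 targets had 9 higher and 6 lower of 23 (11 and 6 adjusted over the list alone; adjusted p = 0.606). Matrix and mesenchymal genes had 9 higher and 7 lower of 28 (10 and 8 adjusted over the list alone; adjusted p = 0.315). The checkpoint genes had 3 higher and 2 lower of 7, also over the list alone (adjusted p = 0.894). Medians, means and tests differed in sign there, with -0.01, -0.10 and an upward test for the p53 targets, -0.11, -0.26 and an upward test for the matrix genes, and -0.81, 0.56 and a downward test for the checkpoint genes. The secreted matrix gene Tgfbi rose from 9.38 ± 0.337 to 55.0 ± 1.09 FPKM while the collagen gene Col5a2 fell from 18.3 ± 0.581 to 2.78 ± 0.267 FPKM.

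Of the 14 lists of markers of other cell types, 13 could be tested in MCA205 cells and camera with the preset correlation called 0 of them, with adjusted p from 0.0711 for fibroblasts up to 0.941 for adipocytes. At an unadjusted p under 0.05 camera gave 1 list, and fry called 1. Single members did change. The fibroblast proteoglycan gene Dcn rose from 14.2 ± 3.41 to 195 ± 3.88 FPKM, the endothelial cadherin gene Cdh5 from 0.572 ± 0.304 to 5.49 ± 0.436 FPKM and the pericyte marker gene Cspg4 from 2.19 ± 0.191 to 11.5 ± 0.341 FPKM. In total the lists had 3 of 13 macrophage genes higher, 2 of 4 dendritic, 2 of 7 endothelial and 1 each of 6 B cell, 7 MHC class II, 8 neutrophil and 5 adipocyte genes. They also had 2 higher and 1 lower of 8 fibroblast genes, and 1 higher and 3 lower of 8 pericyte genes. By edgeR 0 of 6 T cell, 3 epidermis, 6 skeletal muscle, 5 red blood cell and 1 cytotoxic genes were called, with 0 at an unadjusted p under 0.05. DESeq2 called 0 of them, and limma-trend 1 T cell gene with a pseudocount of 1 and 0 with 0.1. Adjusted over the list alone, the macrophage list had 2 higher and the others the same numbers. The medians of the B cell, macrophage, MHC class II, neutrophil, endothelial, fibroblast, pericyte and adipocyte lists lay below 0 while their tests pointed up, and the T cell list had a median of -0.15, a mean of 0.13 and a downward test. Endothelial genes passed without wild type 2, with an adjusted p of 0.026, and fibroblast genes without wild type 1 or wild type 2, with an adjusted p down to 0.000553.

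Transcripts of liver and intestine were present in some MCA205 libraries and nearly absent from others of the same group. The mean FPKM of 12 intestine genes was 0.737, 47.3 and 22.5 in the wild-type libraries and 18.1, 0.0315 and 20.9 in the sgNAT10 libraries. These lists were written after the data were seen. Leaving out wild type 1 and sgNAT10 2 together, the libraries with little of this transcript, gave 3470 higher and 2932 lower genes.

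In sgNAT10 TC1 cells the list of matrix and mesenchymal genes was lower and that of p53 target genes higher. The collagen gene Col5a2 fell from 34.7 ± 3.43 to 0.382 ± 0.0381 FPKM and the retinoic acid binding protein gene Crabp1 from 544 ± 52.4 to 2.64 ± 0.802 FPKM (SD, n = 3). The p53 regulator gene Mdm2 rose from 33.6 ± 1.29 to 127 ± 15.8 FPKM and Cdkn1a, which encodes the p21 cell cycle inhibitor, from 110 ± 9.75 to 368 ± 16.2 FPKM. Among 18823 genes tested, 2991 were higher and 4135 lower, and 908 and 1421 of them changed at least 2-fold. Without wild type 1, sgNAT10 2 or sgNAT10 3 the lower genes numbered 2651, 2516 and 2623, and the share of higher genes among the called, 42.0%, was 54.7%, 53.3% and 53.2%. The excess of lower genes also depended on the scaling. All 6 libraries gave 3389 higher and 3417 lower genes with RLE size factors, and 3773 and 3831 with DESeq2. The median log2 change of all genes moved from -0.08 to -0.01 with RLE size factors. Groups did not overlap for 50.8% of the tested genes, against 10% for chance.

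Among the largest rises in TC1 cells by the fixed rule, Fndc3c1 went from 0.0414 ± 0.0717 to 12.1 ± 0.279 FPKM, the nutrient-sensing GTPase gene Rragb from 0.0222 ± 0.0385 to 6.04 ± 0.353 FPKM and Tro from 0.0485 ± 0.0615 to 7.98 ± 0.365 FPKM. All of them lie on the X chromosome, as does Mageh1 (log2 change 5.70). Acsl6 (6.47), Zbtb7c (6.45), the imprinted zinc finger gene Plagl1 (5.94), Mdfi (5.14), Tusc1 (5.14) and Trim54 (5.08) completed the 10. The falls after Crabp1 included the transcription factor genes Barx1, going from 7.96 ± 0.612 to 0.0425 ± 0.0368 FPKM, Hoxb9 from 63.5 ± 4.91 to 0.682 ± 0.0346 FPKM and Sox2 from 8.87 ± 1.40 to 0.0913 ± 0.0555 FPKM. Grem1, which encodes a secreted inhibitor of bone morphogenetic proteins, went from 80.0 ± 22.5 to 0.792 ± 0.0117 FPKM and Il1rl1, the receptor gene for interleukin 33, from 89.2 ± 58.3 to 0.672 ± 0.216 FPKM. Tex13b (-7.07), Tex101 (-6.66), Car6 (-6.62) and Thbs2 (-6.56) fell as well. Adjusted p of these 20 genes ran from 1.21e-06 for Hoxb9 to 0.000761 for Rragb, and all kept their call in the 6 fits that left 1 library out.

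Interferon-stimulated genes rose in TC1 cells with a wide spread between libraries. On the type I list 31 of 52 genes were higher (36 adjusted over the list alone), with a median of 1.98 (adjusted p = 5.06e-09, and adjusted p = 0.96 with an estimated correlation). Ifi27 rose from 66.3 ± 16.7 to 310 ± 24.4 FPKM and the RNA sensor gene Ifih1 from 2.52 ± 0.767 to 21.7 ± 7.97 FPKM. Nucleic acid sensing genes had 17 higher and 1 lower of 25, also over the list alone (median 0.79, adjusted p = 3.2e-05, and adjusted p = 0.763 with an estimated correlation), among them the DNA sensing adaptor gene Sting1 at 15.8 ± 1.51 against 31.7 ± 0.976 FPKM. The interferon-gamma list had 6 of 21 higher, also over the list alone, and did not pass (adjusted p = 0.218). Irgm1 was its strongest call, from 8.16 ± 3.10 to 54.9 ± 21.9 FPKM. For MHC class I presentation 4 rose and 3 fell of 22, also over the list alone (adjusted p = 0.828), with a median of 0.17, a mean of -0.12 and an upward test. H2-Q6 and H2-Q7, near-identical class I genes that can share reads, fell by 2.81 and 3.73 on the log2 scale. NF-kB targets had 2 higher and 4 lower of 21 (1 and 2 adjusted over the list alone; adjusted p = 0.956), with a median of -0.27 and an upward test, and the adhesion gene Vcam1 fell from 10.7 ± 6.40 to 1.42 ± 0.108 FPKM.

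The p53 targets had 16 higher and 2 lower of 23 in TC1 cells (18 and 2 adjusted over the list alone), with a median of 1.19 (adjusted p = 3.12e-15, and adjusted p = 0.0431 with an estimated correlation). Phlda3 went from 40.9 ± 2.31 to 110 ± 2.15 FPKM. Matrix and mesenchymal genes had 17 lower and 2 higher of 28 (19 and 2 adjusted over the list alone), with a median of -1.09 (adjusted p = 2.40e-20, and adjusted p = 0.0431 with an estimated correlation). The gelatinase gene Mmp2 fell from 14.9 ± 0.511 to 0.651 ± 0.135 FPKM and Snai2, a transcription factor gene of mesenchymal cells, from 20.1 ± 0.196 to 3.74 ± 0.0917 FPKM. The unfolded protein and amino acid stress list had 12 lower and 4 higher of 19, also over the list alone (median -0.76, adjusted p = 3.27e-05, and adjusted p = 0.104 with an estimated correlation). Among its lower members Atf4, a transcription factor gene of the amino acid response, went from 391 ± 19.3 to 146 ± 4.13 FPKM and Chac1 from 130 ± 34.8 to 8.07 ± 0.731 FPKM, while the endoplasmic reticulum gene Sdf2l1 rose from 30.8 ± 3.21 to 128 ± 7.67 FPKM.

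Growth-related lists in TC1 cells passed with the preset correlation and lost their call when it was estimated. MYC targets had 29 lower and 4 higher of 52 (31 and 4 adjusted over the list alone; adjusted p = 0.00238, and adjusted p = 0.96 with an estimated correlation), with the nucleolar gene Nop56 at 354 ± 19.6 against 166 ± 23.9 FPKM. Ribosome biogenesis had 20 lower and 2 higher of 34 (23 and 2 adjusted over the list alone; adjusted p = 0.00218, and adjusted p = 0.96 with an estimated correlation). Cholesterol synthesis had 15 of 19 lower, also over the list alone (median -0.58, adjusted p = 8.5e-05, and adjusted p = 0.96 with an estimated correlation), with Lss at 26.4 ± 3.50 against 12.4 ± 0.566 FPKM. Germline genes had 3 lower and 1 higher of 6 (5 and 1 adjusted over the list alone; adjusted p = 0.00352, and adjusted p = 0.228 with an estimated correlation), and Rhox5 fell from 179 ± 11.6 to 80.4 ± 4.23 FPKM. G1/S genes had 16 higher and 4 lower of 31, also over the list alone (median 0.20, adjusted p = 0.00907, and adjusted p = 0.96 with an estimated correlation). The G2/M list had 12 higher and 1 lower of 27 (16 and 2 adjusted over the list alone; median 0.22, adjusted p = 0.0226, and adjusted p = 0.96 with an estimated correlation). The replicative helicase gene Mcm4 rose from 50.8 ± 3.67 to 95.3 ± 1.24 FPKM and Cdt1, which loads that helicase, fell from 88.2 ± 2.59 to 44.2 ± 1.56 FPKM.

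Several pathway lists were not called by camera in TC1 cells. DNA methylation genes had 4 higher and 4 lower of 17 (4 and 5 adjusted over the list alone; adjusted p = 0.93), with a median of 0.02 and a mean of -0.02. Oxidative phosphorylation had 5 higher and 5 lower of 24, also over the list alone (adjusted p = 0.867). The hypoxia and glycolysis list had 3 higher and 3 lower of 20, also over the list alone (adjusted p = 0.407), with a median of 0.26, a mean of -0.29 and a downward test. Without sgNAT10 1 it passed in the upward direction with an adjusted p of 0.025. Its carbonic anhydrase gene Car9 fell from 89.0 ± 10.6 to 2.09 ± 0.177 FPKM. Checkpoint genes had 2 higher and 1 lower of 9, also over the list alone (adjusted p = 0.38), with a median of -0.04, a mean of 0.02 and an upward test.

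Camera with the preset correlation called 0 of the 14 cell type lists in TC1 cells, with adjusted p from 0.375 for fibroblasts up to 0.963. At an unadjusted p under 0.05 camera gave 0 lists, and fry called 3. In TC1 cells 5 of 14 macrophage genes were higher, among them Cd68, from 6.64 ± 1.34 to 17.9 ± 1.77 FPKM, and 1 of 8 fibroblast genes was higher and 3 lower. Lower genes numbered 1 of 9 for T cells, 2 of 5 for B cells, 1 of 4 for dendritic cells, 1 of 7 for MHC class II, 3 of 8 for pericytes, 2 of 4 for epidermis and 2 of 6 for adipocytes. By edgeR 0 genes were called of 4 cytotoxic, 3 neutrophil, 10 endothelial, 8 skeletal muscle and 6 red blood cell genes. At an unadjusted p under 0.05 these lists had 4 genes, DESeq2 called 4 and limma-trend 0 with either pseudocount. Adjusted over the list alone, 4 fibroblast and 4 pericyte genes were lower and the other numbers did not change. The T cell kinase gene Lck fell from 5.13 ± 0.509 to 0.959 ± 0.195 FPKM, and the epidermal gene Trp63 was listed at 0 in the 3 sgNAT10 libraries. Cytotoxic and endothelial lists had medians of -0.61 and -0.25 with upward tests, and the macrophage list a median of 0.07 with a mean of -0.03. Without wild type 3 the B cell, MHC class II, pericyte and epidermis lists passed, with adjusted p down to 0.0226 for B cells. Liver transcripts were abundant in every TC1 cell library, with albumin (Alb) at 401, 391 and 277 FPKM in wild-type cells and 479, 440 and 383 FPKM in sgNAT10 cells.

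In TC1 tumours the sgNAT10 libraries had more transcript of interferon-induced genes and less of cell cycle genes. As lists, these were called by camera with the preset correlation and not with an estimated one. The interferon-induced GTPase gene Gbp2 rose from 359 ± 116 to 1272 ± 313 FPKM and Tgtp1 from 89.3 ± 35.0 to 449 ± 99.6 FPKM (SD, n = 3). The helicase gene Mcm4 fell from 48.5 ± 3.97 to 21.4 ± 0.773 FPKM and Uhrf1, the partner of Dnmt1 at replicated DNA, from 57.2 ± 4.89 to 22.6 ± 1.62 FPKM. Of 19244 genes tested, 1473 were higher and 1870 lower, and 964 and 548 of them changed at least 2-fold. The groups did not overlap for 40.4% of the tested genes, against 10% for chance. Scaling by library size alone moved the median log2 change of all genes from 0.02 to 0.13 and the share of higher genes among the called from 44.1% to 55.2%. Higher and lower genes numbered 437 and 643 without wild type 2, 388 and 587 without sgNAT10 1, 234 and 321 without sgNAT10 2, and 414 and 492 without sgNAT10 3.

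The largest rise in the tumours was that of the bone morphogenetic protein gene Bmp5, from 0.0649 ± 0.0571 to 8.99 ± 1.24 FPKM, followed by the RNA export gene Nxf3, from 0.0732 ± 0.0637 to 8.27 ± 1.51 FPKM. Aldh1a1, which makes retinoic acid, went from 0.962 ± 0.782 to 29.5 ± 5.32 FPKM and the muscle and fat carbonic anhydrase gene Car3 from 1.12 ± 0.326 to 11.6 ± 0.675 FPKM. H2-M10 (log2 change 6.37), Ostn (5.67), Csta2 (3.73), the fat cell gene Cfd (3.53) and Dach2 (3.30) rose too. Mup10, of a liver-expressed multigene family whose members share reads, rose from 1.24 ± 1.19 to 15.8 ± 14.8 FPKM. The mean of 12 liver genes moved with it, at 0.124, 5.41 and 20.9 FPKM in the wild-type tumours and 49.8, 56.7 and 52.1 FPKM in the sgNAT10 tumours. Prkar1b fell from 5.61 ± 0.731 to 0.452 ± 0.0432 FPKM, the laminin gene Lama5 from 5.31 ± 1.01 to 0.681 ± 0.0472 FPKM and Tspan6 from 19.4 ± 1.92 to 2.98 ± 0.408 FPKM. Nme4 (-3.46), Galnt18 (-3.44), the granzyme gene Gzmg (-2.96), Prss22 (-2.90), the retinoic acid binding protein gene Crabp2 (-2.73), the arginine transporter gene Slc7a3 (-2.59) and Ddah2 (-2.54) were the other falls. Adjusted p ranged from 0.000471 for Lama5 to 0.0475 for Mup10. Calls were lost for Mup10, Cfd, Gzmg and Prss22 without sgNAT10 1, for Ostn, Mup10, Gzmg and Prss22 without sgNAT10 2, for these and Cfd without sgNAT10 3, and for Mup10 and Cfd without wild type 2.

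Interferon lists rose in the tumours, and none of the list calls in this comparison held with an estimated correlation. Type I interferon-stimulated genes had 43 higher and 1 lower of 52 (49 and 1 adjusted over the list alone; median 1.14, adjusted p = 1.06e-29, and adjusted p = 0.417 with an estimated correlation). The antiviral gene Rsad2 went from 21.6 ± 4.74 to 51.8 ± 1.59 FPKM and Xaf1 from 39.5 ± 5.58 to 98.6 ± 1.39 FPKM. The member that fell was Nmi, from 39.9 ± 6.03 to 21.3 ± 1.22 FPKM. The interferon-gamma list had 17 of 21 higher (20 adjusted over the list alone; median 1.43, adjusted p = 3.69e-17, and adjusted p = 0.417 with an estimated correlation), with Cd274, which encodes the checkpoint ligand PD-L1, at 13.9 ± 3.23 against 39.6 ± 9.34 FPKM. Nucleic acid sensing had 9 of 26 higher (10 adjusted over the list alone; adjusted p = 0.000393, and adjusted p = 0.606 with an estimated correlation). MHC class I presentation had 6 of 22 higher (9 adjusted over the list alone; adjusted p = 0.000786, and adjusted p = 0.662 with an estimated correlation). Nlrc5, a transactivator of class I genes, rose from 20.9 ± 5.64 to 44.4 ± 2.14 FPKM. NF-kB targets had 6 higher and 1 lower of 22 (8 and 1 adjusted over the list alone; adjusted p = 0.0228, and adjusted p = 0.474 with an estimated correlation), a call lost without wild type 2 (adjusted p = 0.102). Its chemokine gene Cxcl10 rose from 426 ± 156 to 915 ± 88.7 FPKM. Of the 87 called list members chosen by the rule in this comparison, 49, 55 and 49 were not called without sgNAT10 1, 2 and 3, and 15, 47 and 3 without wild type 1, 2 and 3.

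Proliferation and biosynthesis lists fell in the tumours. All 27 G2/M genes were lower, also over the list alone (median -1.04, adjusted p = 9.75e-31, and adjusted p = 0.344 with an estimated correlation), with the mitotic kinase gene Plk1 at 44.2 ± 3.44 against 19.2 ± 2.44 FPKM. G1/S genes had 28 of 31 lower (30 adjusted over the list alone; median -1.03, adjusted p = 5.18e-34, and adjusted p = 0.307 with an estimated correlation). MYC targets had 25 of 52 lower (38 lower and 1 higher adjusted over the list alone; median -0.59, adjusted p = 1.33e-15, and adjusted p = 0.474 with an estimated correlation). Ribosome biogenesis had 16 of 34 lower (27 adjusted over the list alone; adjusted p = 1.20e-09, and adjusted p = 0.474 with an estimated correlation). Tbl3, of the small subunit processome, went from 13.8 ± 0.895 to 8.57 ± 0.0648 FPKM. The DNA methylation machinery had 6 lower and 1 higher of 17, also over the list alone (adjusted p = 0.0109, and adjusted p = 0.417 with an estimated correlation), among them the chromatin remodeller gene Hells at 28.6 ± 3.70 against 14.5 ± 2.16 FPKM. Hypoxia and glycolysis had 2 of 20 lower (8 adjusted over the list alone; adjusted p = 0.000786, and adjusted p = 0.693 with an estimated correlation). Oxidative phosphorylation had 3 of 24 lower, also over the list alone (adjusted p = 0.00404, and adjusted p = 0.693 with an estimated correlation), a call lost without wild type 1 (adjusted p = 0.19).

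Not called by camera in the tumours was the germline list (adjusted p = 0.305), which fry called upward (adjusted p = 0.028), with 0 of 8 members called by edgeR, 3 at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma-trend with either pseudocount. The p53 targets had 2 higher and 2 lower of 23 (4 and 2 adjusted over the list alone; adjusted p = 0.608). The unfolded protein and amino acid stress list had 5 higher and 4 lower of 19 (6 and 4 adjusted over the list alone; adjusted p = 0.47). Cholesterol synthesis had 2 of 19 lower, also over the list alone (adjusted p = 0.117). Matrix and mesenchymal genes had 3 higher and 3 lower of 28, also over the list alone (adjusted p = 0.608). Among them the matricellular gene Postn rose from 45.8 ± 18.4 to 250 ± 30.5 FPKM and the smooth muscle actin gene Acta2 fell from 47.9 ± 19.7 to 9.19 ± 1.29 FPKM. The checkpoint list had 3 higher and 2 lower of 11, also over the list alone (adjusted p = 0.47), with Ctla4 going from 1.20 ± 0.409 to 3.24 ± 0.642 FPKM and Tigit, another inhibitory receptor of T cells, from 36.4 ± 13.3 to 10.1 ± 0.662 FPKM. Cholesterol synthesis passed without wild type 1 or sgNAT10 2, with an adjusted p down to 0.00956.

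Some lists of cell type markers moved with the genotype in the tumours, beside the interferon and cell cycle lists. The mean of 12 liver genes was also higher in each sgNAT10 tumour than in each wild-type tumour. Since organ transcripts were found in cultured cells too, it is not shown that these markers come from host cells. With the liver and intestine covariate 2436 of the 3343 called genes kept their call and direction. Skeletal muscle genes had 7 of 10 higher (10 adjusted over the list alone; median 1.94, adjusted p = 3.77e-11, and adjusted p = 0.307 with an estimated correlation), with the actin gene Acta1 at 51.8 ± 16.1 FPKM in sgNAT10 tumours. Endothelial genes had 7 of 10 higher (8 adjusted over the list alone; adjusted p = 0.00111, and adjusted p = 0.474 with an estimated correlation), with Pecam1 at 14.9 FPKM against 25.2 FPKM. Cytotoxic and NK cell genes had 2 of 14 higher (3 adjusted over the list alone; adjusted p = 0.0244, and adjusted p = 0.693 with an estimated correlation), among them Ifng, which encodes interferon gamma, from 2.56 ± 0.584 to 6.32 ± 2.09 FPKM. That list was not called without wild type 2 (adjusted p = 0.139) or without wild type 1. Red blood cell genes had 4 of 5 lower (5 adjusted over the list alone; median -1.91, adjusted p = 0.00185, and adjusted p = 0.474 with an estimated correlation), with the globin gene Hbb-bs, which shares reads with its neighbours, at 121 ± 51.7 against 36.2 ± 8.03 FPKM.

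The other cell type lists were not called by camera in the tumours. T cell genes had 2 of 16 higher (0 adjusted over the list alone; adjusted p = 0.0824), B cell genes 1 of 6 higher (adjusted p = 0.47), macrophage genes 2 of 14 lower (adjusted p = 0.706) and neutrophil genes 1 of 9 lower (adjusted p = 0.824). The macrophage lysozyme gene Lyz2 fell from 545 ± 31.3 to 331 ± 35.7 FPKM. Dendritic cell genes (0 of 10, adjusted p = 0.0984), MHC class II (0 of 7, adjusted p = 0.123) and epidermis (0 of 6, adjusted p = 0.181) had no called member by edgeR. At an unadjusted p under 0.05 they had 3, 1 and 2 genes, DESeq2 called 2, 1 and 0, and limma-trend 2, 0 and 0 with either pseudocount. Fibroblast genes had 2 higher and 1 lower of 8 (adjusted p = 0.316). Pericyte genes had 1 higher and 1 lower of 8 (3 and 1 adjusted over the list alone; adjusted p = 0.763) with a median of 0.16 and a mean of -0.26. Adipocyte genes had 1 of 5 higher (3 adjusted over the list alone; adjusted p = 0.0621). Adjusted over the list alone, the B cell, macrophage, neutrophil, dendritic, MHC class II, epidermis and fibroblast numbers did not change. Without wild type 3 the T cell, dendritic and MHC class II lists passed, with adjusted p down to 0.0122 for T cells, as did T cells without sgNAT10 1 and MHC class II without sgNAT10 3. Fibroblast, epidermis and adipocyte lists passed without sgNAT10 2, and adipocytes also without wild type 1 or wild type 2, with adjusted p down to 0.000129 for adipocytes.

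Camera with the preset correlation called 10, 11 and 16 of all lists in MCA205 cells, TC1 cells and tumours, of which 3, 2 and 0 were also called with an estimated correlation. Of the 19 pathway lists fry called 16, 9 and 9, where camera called 10, 11 and 12. Fry thus called more of them in MCA205 cells and fewer in TC1 cells and tumours. Other splits of the same 6 libraries gave up to 22, 18 and 21 list calls, so the number of list calls does not set the real split apart. Groups of these splits hold unequal numbers of each genotype and keep part of its difference. They thus do not measure the spread between libraries alone, and cannot decide whether a list call exceeds it.

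**Figure D2:**
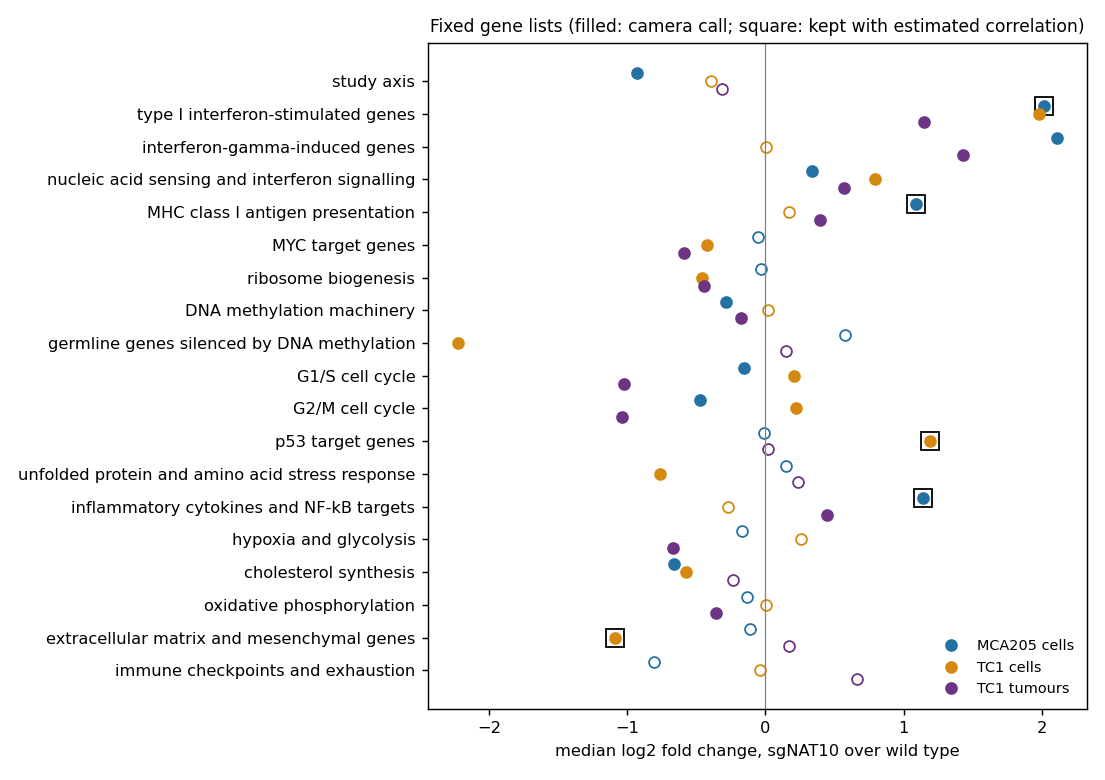
Median log2 fold change (sgNAT10 over wild type, linear axis) of the members of each of the 19 fixed pathway lists in MCA205 cells, TC1 cells and TC1 tumours (3 libraries per group), with filled points for lists called by camera with the preset correlation and a square around those also called with an estimated correlation. Type I interferon-stimulated genes lie at 2.01, 1.98 and 1.14, and G2/M genes at -0.47, 0.22 and -1.04.

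Some genes abundant in cultured TC1 cells and absent from MCA205 cells were nearly absent from the TC1 tumours. The imprinted growth regulator gene Dlk1 was at 301 ± 37.4 and 335 ± 30.4 FPKM in wild-type and sgNAT10 TC1 cells, at 0 in MCA205 cells, and at 0.985 ± 0.147 and 0.394 ± 0.197 FPKM in the corresponding tumours. The germ cell gene Rbm46 was at 25.4 and 24.5 FPKM in TC1 cells and listed at 0 in the tumours. These genes belong to a group of 11 with at least 10 FPKM in every TC1 cell library, varying at most 3-fold among them, and less than 0.5 FPKM in every MCA205 library, a rule chosen after the data were seen. Their level in wild-type tumours had a median of 0.327% of that in wild-type TC1 cells, with a range from 0 to 8.30%.

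**Figure D3:**
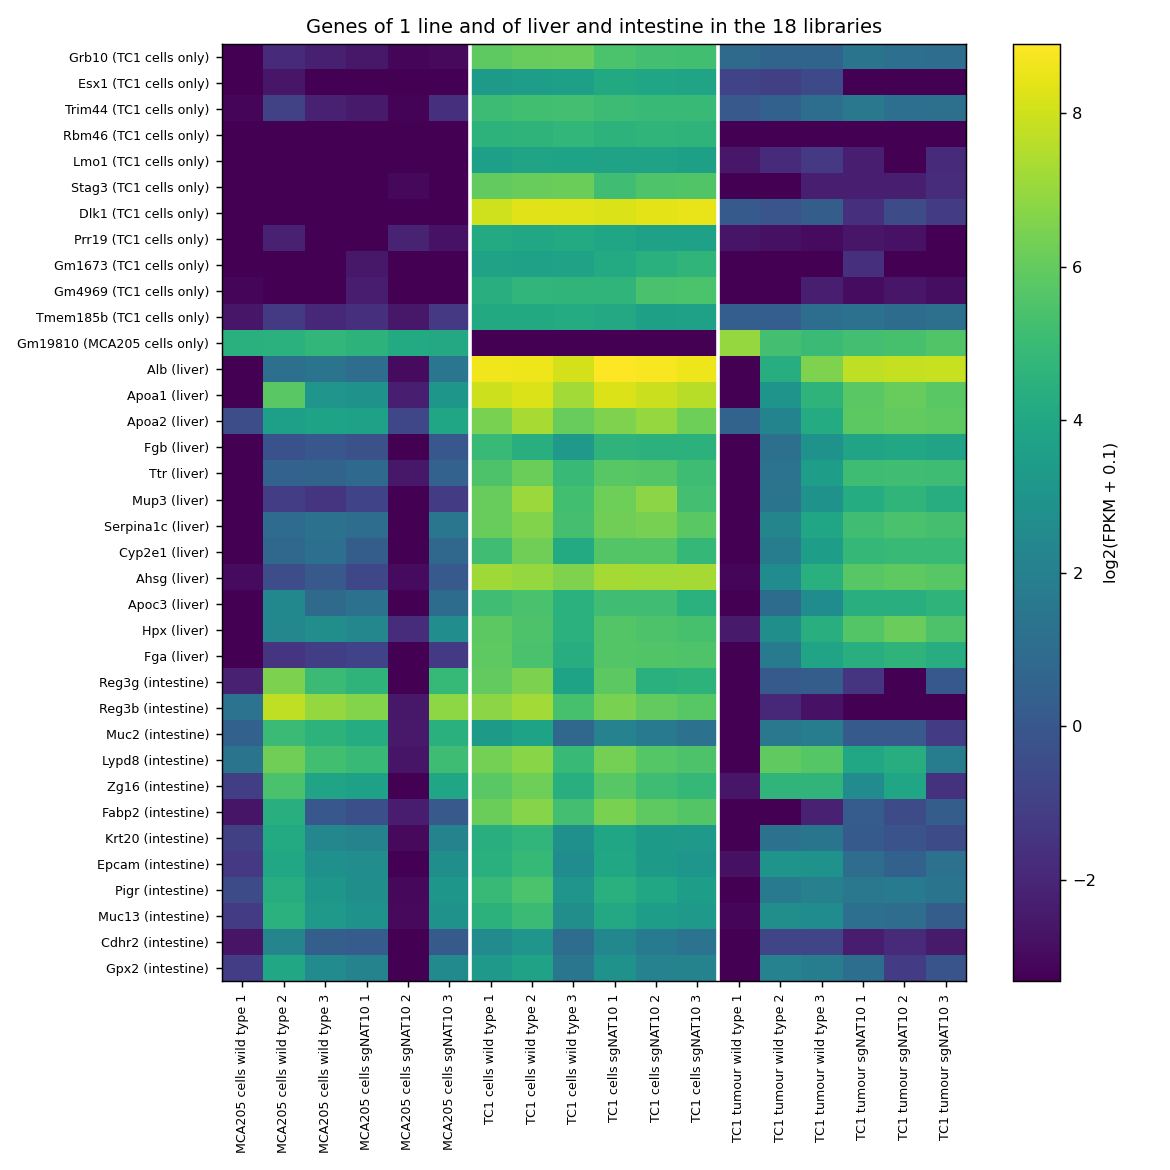
Heat map of log2(FPKM + 0.1), given by colour, of genes found in 1 cell line and not in the other and of liver and intestine genes (vertical) in each of the 18 libraries (horizontal), with white lines between MCA205 cells, TC1 cells and TC1 tumours. Dlk1 has a mean of 301 FPKM in wild-type TC1 cells and 0.985 FPKM in wild-type tumours, and the mean of the liver genes runs from 0.124 to 20.9 FPKM among wild-type tumours.

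The sgNAT10 effect, the difference between libraries labelled sgNAT10 and wild type, differed between MCA205 and TC1 cells for 7247 of 20504 genes. Between TC1 tumours and TC1 cells it differed for 5506 of 21112 genes, both by a test of the difference itself. Differences between cell populations that arose apart from the guide would enter these numbers too. Without replicate 2 in every group these numbers were 4190 and 1701, and the former was 4410 without replicate 3. Dnmt1 fell further in MCA205 than in TC1 cells (difference -0.94, adjusted p = 7.75e-06), as did Cdk2 (-0.79, adjusted p = 0.00844), while no difference was called for Myc (-0.24, adjusted p = 0.263). The type I interferon list did not pass for a difference between the cell lines (adjusted p = 0.804, median difference -0.05). Matrix and mesenchymal genes passed (adjusted p = 2.04e-15, and adjusted p = 0.0287 with an estimated correlation), with Mmp2 higher in sgNAT10 MCA205 cells, at 29.9 against 83.5 FPKM, and lower in sgNAT10 TC1 cells. G2/M genes (adjusted p = 3.02e-13, and adjusted p = 0.3 with an estimated correlation), p53 targets (adjusted p = 1.89e-06, and adjusted p = 0.186 with an estimated correlation) and the stress response list (adjusted p = 4.49e-06, and adjusted p = 0.186 with an estimated correlation) passed with the preset correlation. So did G1/S genes (adjusted p = 1.83e-05, and adjusted p = 0.945 with an estimated correlation) and germline genes (adjusted p = 0.00277, and adjusted p = 0.186 with an estimated correlation). DNA methylation genes (adjusted p = 0.0195, and adjusted p = 0.692 with an estimated correlation) and ribosome biogenesis (adjusted p = 0.0314, and adjusted p = 0.981 with an estimated correlation) passed likewise. Between TC1 tumours and TC1 cells G1/S genes (adjusted p = 1.66e-28, and adjusted p = 0.0459 with an estimated correlation), p53 targets (adjusted p = 4.08e-07, and adjusted p = 0.0451 with an estimated correlation) and matrix genes (adjusted p = 4.41e-12, and adjusted p = 0.0088 with an estimated correlation) differed. Passing with the preset correlation alone were G2/M genes (adjusted p = 2.45e-23, and adjusted p = 0.122 with an estimated correlation) and the stress response list (adjusted p = 0.000453, and adjusted p = 0.273 with an estimated correlation). The type I interferon list was among them, with a median difference of -1.07 (adjusted p = 0.00951, and adjusted p = 0.767 with an estimated correlation), as were skeletal muscle genes (adjusted p = 0.0024, and adjusted p = 0.7 with an estimated correlation).

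Overlaps of calls were set against those of independent lists. Of the 4525, 4705 and 4811 tested genes with the fewest counts, 11.3%, 12.4% and 7.59% were called in MCA205 cells, TC1 cells and tumours. Among the 4526, 4706 and 4811 with the most counts, 63.3%, 57.0% and 24.7% were called. The hypergeometric test takes every gene as equally likely to be called, so its p can be small without a shared response. MCA205 and TC1 cells had 849 genes higher in both, where independent lists would share 604 (exact hypergeometric p = 8.14e-33), and 1079 lower in both, where 810 would be shared (p = 1.52e-32). Genes higher in MCA205 and lower in TC1 cells numbered 1076, against 858 (exact hypergeometric p = 3e-21), and the reverse 675, against 570 (p = 6.49e-08). Across genes, which are not independent replicates, the log2 changes had a Pearson r of -0.05 and a Spearman rho of 0.02. Dipk1b, Arhgap31, the caspase inhibitor gene Xiap, Eno3 and Zbtb33 rose in both lines, and Col5a2, Acsl3, Trim24, Sox2 and Olfml2b fell in both. Mmp2, Ltbp4, Lpcat2, Grem1 and the glypican gene Gpc1 were called in opposite directions. TC1 cells and tumours had 216 genes higher in both, against 208 for independent lists (p = 0.282), and 576 lower in both, against 426 (p = 9.51e-18), with r of -0.06 and rho of 0.01. Genes higher in TC1 cells and lower in tumours numbered 409, against 304 (exact hypergeometric p = 1.28e-11). The reverse numbered 258, against 291 (exact hypergeometric p = 0.991 for a larger and p = 0.0111 for a smaller overlap). Akr1b10, Etv1, Eda2r, Ifit2 and Parp9 were higher in both, and Cdt1, Msln, Rab12, Sgo1 and Cenpn lower in both. Cell cycle genes made up the opposite calls with the smallest p, namely Mcm4, Cep55, Gtse1, Ccnf and E2f8.

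A run of neighbouring genes on chromosome 5 rose in sgNAT10 TC1 cells and in neither of the other comparisons as a group. Between positions 8037294 and 9160986 of mm10, 13 genes were at least 8-fold higher, out of 21 tested in the surrounding window from 7000000 to 10000000. Among tested genes within that span that were less than 8-fold higher, 7330423F06Rik, which lies inside Abcb1b, rose by less (log2 change 2.82, adjusted p = 0.0408), and Abcb4 and Gm17936 were not called, with log2 changes of 0.88 and 0.55 and adjusted p of 0.0952 and 0.53. At the edge Dmtf1 rose by 1.90 on the log2 scale (adjusted p = 2.66e-05). Dbf4, the activator of the replication kinase Cdc7, rose from 44.1 ± 5.73 to 869 ± 26.9 FPKM, the calcium-binding protein gene Sri from 33.4 ± 2.18 to 635 ± 30.4 FPKM and the peroxisomal gene Crot from 16.3 ± 1.48 to 302 ± 41.8 FPKM. The drug transporter gene Abcb1a rose from 3.45 ± 0.146 to 81.9 ± 7.96 FPKM, with reads that can be shared with its paralog Abcb1b, and Tmem243 overlaps its raised neighbour Dmtf1, so their split is uncertain without strand. Over all tested genes from the first to the last of the 13, the median log2 change was 4.23 in TC1 cells, -0.03 in MCA205 cells and 0.02 in the tumours. Among the 13, Gm42685 was listed at 0 in wild-type cells, so its fold is uncertain. It lies inside Rundc3b and Gm42686 inside Abcb1a, while Gm15731 overlaps Sri and Gm5106 overlaps Abcb1b. Without strand the rises of these models may come from reads of the raised genes they overlap. The block was chosen for description after its values were seen, since Sri, Dbf4, Crot and Tmem243 were among the genes with the smallest p for a difference between comparisons.

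**Figure D4:**
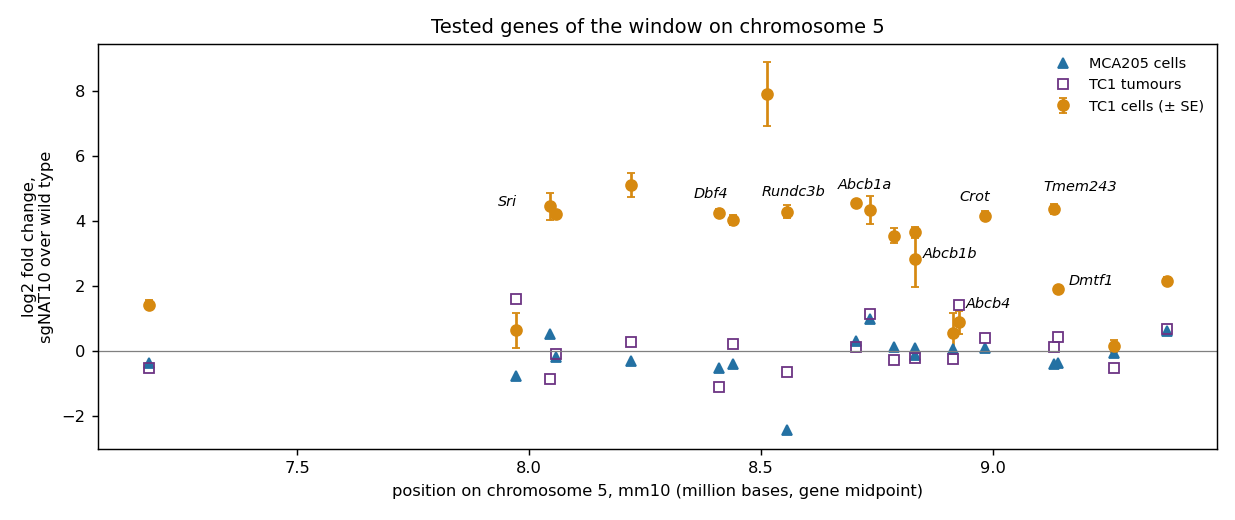
Log2 fold change (sgNAT10 over wild type, linear axis) against position on chromosome 5 of mm10 in megabases, for tested genes of the window in MCA205 cells, TC1 cells and TC1 tumours, with bars of 1 SE for TC1 cells and 3 libraries per group. In TC1 cells 13 genes stand at least 8-fold higher, and the median over the tested genes of the span is 4.23, against -0.03 in MCA205 cells.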

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

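Of the tests in this part, those of the tumours' origin and of expression in general, those of the chromosome 5 genes, and the pair of MCA205 cells and tumours were chosen after the result was seen.

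The effect of sgNAT10 differed between MCA205 and TC1 cells for 7247 genes, between TC1 tumours and TC1 cells for 5506 genes, and between MCA205 cells and tumours for 4391 genes, by the interaction test. Without replicate 2 in every group these numbers were 4190, 1701 and 841. Without replicate 3 the first was 4410 and the last 2536, and the last was 2912 without replicate 1 and 2618 with a replicate block. Of 100 regroupings of the genotype within each table, 2 gave as many genes for each of the first 2 pairs, the real one included. The highest others, 7364 and 5654 genes, came from the regrouping that swaps the genotype of 1 whole table. The next highest were 3195 and 2749. Regroupings that mix the genotypes within a table weaken any genotype effect, so they bear on whether genotype matters and not on whether effects differ. Chance as a source of these differences is thus not excluded. Nor are differences between the cell populations that arose apart from the guide.

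The fall of Dnmt1 was larger in MCA205 than in TC1 cells, with a difference of -0.94 on the log2 scale, as was that of Cdk2, with -0.79. Between tumours and TC1 cells the difference for Cdk2 was 0.68 (adjusted p = 0.0176), the fall being smaller in tumours. With the smallest p, the effect was higher in MCA205 than in TC1 cells for Hoxb9 (7.60), Gpc1 (3.19), Mmp2 (6.11), Adgra2 (2.42) and Bgn (5.97), and lower for Sri (-4.46), Dbf4 (-4.84), Crot (-4.14), Tmem243 (-4.82) and Alas1 (-1.58). It was higher in tumours than in TC1 cells for Thbs2 (7.50), Bgn (6.73), Zfp979 (5.98), Sema3a (5.31) and Pcdh19 (4.36), and lower for Sri (-4.32), Dbf4 (-5.37), Tmem243 (-4.25), Crot (-3.80) and Ydjc (-5.01).

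For the counts of called genes, the 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 of 10 with the most genes in each comparison, with 7355, 7126 and 3343 genes called by edgeR in MCA205 cells, TC1 cells and tumours against at most 0, 1 and 0 in the 9 others. At an unadjusted p under 0.05 the real splits had 8681, 8707 and 6667 genes and the others at most 308, 873 and 861. For list calls the splits are likewise too few, and 7, 6 and 5 of the 10 splits gave as many lists as the real one, with 10, 11 and 16 lists called against at most 22, 18 and 21.

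Genes found in TC1 cells and not in MCA205 cells were nearly absent from the TC1 tumours, with a median of 0.327% of their level in wild-type TC1 cells. Few tumour cells among host cells are argued against as the whole cause, since G2/M genes stood at a median of 104.9% of their level in TC1 cells, though dividing host cells could add to that. A lower expression in the mouse in general was tested with 10000 random lists of genes of the same level that both lines express. Of these lists, 0% lay as low. Host cells can also express genes that both lines share, which would hold such lists up, so this test cannot decide. Tumours grown from other cells than the TC1 cells, as with a mislabelled sample, may account for the pattern, since 93.75% of 64 genes at least 8-fold higher in wild-type MCA205 than in TC1 cells, and 83.9% of 112 at least 8-fold higher in TC1 cells, lay nearer to MCA205 in the wild-type tumours. The genes counted had a mean of at least 5 FPKM in the higher wild-type line and varied at most 3-fold over its 6 libraries, organ genes left out. Only 1 gene, the pseudogene Gm19810, was found steadily in MCA205 and not in TC1 cells. It stood at 65.0 ± 51.5 FPKM in wild-type tumours. The origin of the tumours stays open, because host cells express some of these genes too, and silencing of just these genes in the mouse was not tested.

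Transcripts of liver and intestine were found in cultured cells. Between libraries of a group the mean of the intestine genes differed by 64.1-fold in wild-type and 663-fold in sgNAT10 MCA205 cells, and by 3.87-fold and 1.82-fold in TC1 cells. That of the liver genes differed by 129-fold and 45.5-fold in MCA205 cells, and by 1.91-fold and 1.32-fold in TC1 cells, where it lay between 65.6 and 125 FPKM. Where these transcripts came from was not tested.

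The raised genes on chromosome 5 in sgNAT10 TC1 cells are not accounted for by reads shared between the paralogs Abcb1a and Abcb1b. Among the other genes 11 were at least 8-fold higher, though some of them overlap another raised gene or a paralog. Dbf4, Slc25a40 and Crot overlap no other raised gene. A response to NAT10 targeting in any cell is argued against by a median of -0.02901 in MCA205 cells. More copies in the sgNAT10 TC1 cells from which the tumours grew are argued against by a median of 0.01533 in the tumours. That value does not bear on the cultured cells if the tumours grew from others, so more copies in the cultured cells stay open, and no DNA was analysed here. A response of TC1 cells in culture alone was not tested.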

How the results depend on the processing

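The liver and intestine covariate, the fit without a pair of MCA205 libraries and the pair of MCA205 cells and tumours were chosen after the result was seen. Of the counts of genes and lists, 145 stayed within 1.5 times and 47 moved further. Of the list results 788 stayed on their side of the threshold, 48 passed newly and 45 no longer passed. Of the named gene results 6234 stayed on their side, 113 passed newly and 517 no longer passed. A change of sign where neither fit was called was counted as staying, so direction was not always kept. For the changes given here the cause was not tested, except where fewer genes or libraries enter by construction.

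With dispersion over all 18 libraries MCA205 cells had 2131 lower genes, and tumours 2433 higher and 3079 lower. A 2-fold minimum left 1170 higher and 619 lower genes in MCA205 cells, 908 and 1421 in TC1 cells, and 964 and 548 in tumours. In tumours library size alone gave 1223 lower genes, no filter 870 higher, DESeq2 2406 higher and limma-trend on log2(FPKM + 0.1) 1240 lower. Genes called in the same direction numbered 240, 148 and 324 at a 2-fold minimum for MCA205 and TC1 cells, TC1 cells and tumours, and MCA205 cells and tumours, and in opposite directions 292, 161 and 76, against 1751, 667 and 444 opposite without that minimum. For the latter pairs the same direction had 1205 and 2118 with DESeq2 and 398 and 882 without a filter, and the opposite 1173 and 841, and 419 and 307. With an estimated correlation camera called 5 pathway lists and 0 cell type lists.

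Leaving out 1 library gave 2516 to 3801 lower genes in TC1 cells, with 2516 without sgNAT10 2, and in tumours 234 to 2191 higher and 321 to 2421 lower, lowest without sgNAT10 2 and highest without wild type 3. The title gene tests were counted with the same-named library left out of all 3 comparisons at once. Of these tests 4 to 6 were called, with 4 without sgNAT10 2 or sgNAT10 3, against 8 with all libraries. Differences of effects were refitted with 1 replicate number left out of every group. They numbered 4190 to 6314 for MCA205 and TC1 cells and 1701 to 5173 for TC1 cells and tumours. For MCA205 cells and tumours they numbered 841 to 2912, and each range was lowest without replicate 2. With 1 library left out of 1 comparison, cell type lists called numbered 4 to 8, with 8 without TC1 wild type 3. Reversed were Krt14 in MCA205 cells, not called with all libraries, which ranged from -4.05 to 9.09 on the log2 scale, highest without wild type 2, the TC1 hypoxia and glycolysis list, whose adjusted p ranged from 0.025 without sgNAT10 1 to 0.867, and Retnlg in tumours, at 1.99 with the covariate. With the covariate MCA205 cells had 4099 higher and 3896 lower genes, TC1 cells 2881 and 3925, and tumours 1244 and 1640.

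Equal replicate numbers did not pair the libraries, as the correlations of same-numbered deviations lay between -0.549 and 0.269 and no library correlated best with its own number. A replicate block gave 3043 higher and 2646 lower genes in MCA205 cells, 2306 and 3399 in TC1 cells, 360 and 476 in tumours, and 2618 differences for MCA205 cells and tumours. In the 4525, 4705 and 4811 tested genes with the fewest counts the median SE of the log2 change was 0.633, 0.56 and 0.617 in MCA205 cells, TC1 cells and tumours, against 0.0444, 0.0775 and 0.135 in the 4526, 4706 and 4811 with the most, so low counts limit what can be called.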

Other observations

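The pair of MCA205 cells and tumours, the organ lists and the description of Pvt1 were chosen after the result was seen.

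MCA205 cells and TC1 tumours shared more calls than independent lists would, by a test that takes every gene as equally likely to be called. Genes higher in both numbered 518, against 267 for independent lists (exact hypergeometric p = 4.77e-63), and genes lower in both 820, against 376 (p = 2.39e-137). Genes higher in tumours and lower in MCA205 cells numbered 112, against 249.9, and the reverse 332, against 402. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.20 and a Spearman rho of 0.18, and r was 0.0297 without the expression filter. Of 1782 genes called in both, 75.1% had the same direction. Isg20, Rsad2 and Xaf1, which are induced by interferon, were among those higher in both, with Mtm1 and Fendrr, and the laminin gene Lama5, the lamin gene Lmnb1, Stra6, Amigo2 and Ddah2 were lower in both. By camera on the difference of effects, the type I interferon list rose less in tumours (median difference -0.93, adjusted p = 1.35e-17, and adjusted p = 0.604 with an estimated correlation). The effect was also lower in tumours for G1/S genes (adjusted p = 2.57e-20, and adjusted p = 0.249 with an estimated correlation) and MYC targets (adjusted p = 3.99e-08, and adjusted p = 0.875 with an estimated correlation).

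Pvt1, a long noncoding RNA gene beside Myc on chromosome 15 from 62037986 to 62378096, rose in sgNAT10 TC1 cells from 15.4 ± 1.43 to 309 ± 20.3 FPKM (SD, n = 3, edgeR adjusted p = 4.01e-06), while Myc fell by 0.43 on the log2 scale. Its log2 change was 0.51 in MCA205 cells (adjusted p = 0.00405) and -0.44 in the tumours (adjusted p = 0.288).

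Of the organ lists, liver had 0 of 12 genes called by edgeR in MCA205 cells and in TC1 cells and 1 of 12 higher in tumours, where its median log2 change was 2.58. Intestine had 0 of 12 called in both cell lines and 1 of 11 higher in tumours, where its median log2 change was -1.36. Brain genes had 2 of 3 higher in TC1 cells, and kidney and heart genes had none called. The mean of 4 brain genes there was 0.33, 0.4 and 0.414 FPKM in wild-type libraries. In sgNAT10 libraries 1, 2 and 3 it was 0.362, 5.04 and 3.9 FPKM, so the rise rests on sgNAT10 2 and 3. Over the organ lists with no called gene, 1, 1 and 0 genes of MCA205 cells, TC1 cells and tumours had an unadjusted p under 0.05. DESeq2 called 1, 1 and 0 of them, and limma-trend 0, 1 and 0 with either pseudocount. Airway genes were not tested. The mean of 4 kidney genes in TC1 cells was 34.5, 39.9 and 2.56 FPKM in wild-type libraries and 6.12, 4.66 and 47.9 FPKM in sgNAT10 libraries.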
